A study of Mus musculus with 6 samples.

How the data were processed

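Gene expression was measured by 3' mRNA sequencing (QuantSeq, which primes at the poly(A) tail so that a transcript yields about 1 read position near its 3' end) in 6 libraries of sorted mouse T cells, 3 from L-Pha low cells and 3 from L-Pha high cells. Groups and the leading number of each library (1, 2 or 3) were taken from the labels. The labels say that tumours were pooled but not whether the 3 libraries of a group came from separate pools or animals, so p-values measure the spread between these libraries, which may be technical.

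The deposited count table holds whole-number read counts per gene, made by the authors with featureCounts 1.5.0-p3 on the GRCm38 gene models of Ensembl release 78, per the file headers. The options recorded there count reads on the sense strand, count a read with several alignments at each of them, and assign a read to every gene it overlaps. Near-identical genes, such as the granzymes Gzmc to Gzmg, Klrc1 and Klrc2, ribosomal protein genes and their copies, and the small nuclear RNA genes, therefore share reads, and their values are uncertain as separate genes. The submitters' processing notes list bcl2fastq 2.17.1.14, FastQC 0.11.5, cutadapt 1.7, HISAT2 2.1.0, Subread 1.5.0 and limma without a version or a role. The same notes name the human build hg19, whereas the count table's header and its mouse gene identifiers name GRCm38; coordinates are given on GRCm38 as in the count table. A deposited table of log2 values, with 14293 gene symbols, was made by the authors in a way not given in the sources used here. Raised to the power of 2, its values were a straight-line function of the counts in each library, with implied library sizes from 2280634 to 3013711. It was used for 1 alternative only. Gene symbols and gene types came from GENCODE M21, also on GRCm38, in which 97.3% of the 43629 gene identifiers had a symbol. All columns of per-sample values were used.

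Library totals ran from 2610729 to 3521117 counts. Of 43629 genes, 21866 had a count and 11183 passed edgeR's filterByExpr and were tested. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, group as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD, and log2 fold changes are L-Pha high minus L-Pha low, given with a standard error (SE) derived from the F statistic. Exact binomial (Clopper-Pearson) 95% intervals of shares and of ratios of summed counts cover counting error only. Reads carried no molecular identifier in the sources used here, so they are not independent molecules.

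In advance, 30 gene lists with 693 symbols were fixed, covering glycan enzymes, T cell states, growth, interferon response, RNA quality, T cell identity and other cell types of a tumour; 692 symbols matched. The 29 lists with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The counts adjusted over the list alone apply the same adjustment to the edgeR p-values of that list's members. Genes to be named were also fixed by a rule: up to 12 genes per direction past the threshold with a mean of at least 5 CPM and no overlap between groups, filled up to the 5 with the smallest p where fewer passed, leaving out receptor segments, predicted genes and genes with no symbol; up to 4 members of each list with the smallest p; and 16 genes of the glycan pathway, T cell identity and T cell state. Genes named outside the rule are said to be so, and 1 gene that the rule names is not reported here.

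On counts simulated for this comparison from the observed means, dispersions and library sizes, with 200 of the genes changed, edgeR's step ran on 10765 genes. It recovered 21% of the 100 genes changed 2-fold and 81% of the 100 genes changed 4-fold, with 6 false calls. The cut-off set by the adjustment depends on how many genes change, so these shares do not carry over to data in which fewer change. With no gene changed it made 0 calls. A list shifted 1.5-fold in simulated counts was called by camera, with 0 of the 28 other lists. The simulation put in no correlation between the genes of a list. In the real counts the estimated inter-gene correlation ran from -0.0173 for the secretory pathway list to 0.908 for the T cell identity list. The simulated lists therefore cannot show how often camera at the preset correlation calls unchanged lists in the real libraries.

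Alternatives fixed beforehand were DESeq2's size factors in edgeR, scaling by library totals alone, no filter on low counts, a stricter filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on the deposited log2 table, thinning to the smallest library total, leaving out receptor segment genes, a block on the libraries' numbers, and leaving out each library. For the lists they were camera with an estimated correlation, fry, library totals alone, the stricter filter, the block and leaving out each library. A covariate for T cell identity transcripts and a restriction to protein-coding genes were added after seeing the data. The choices listed before these 2 were made before the data were examined.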

Results

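Tumour-infiltrating T cells were taken from pooled subcutaneous B16-OVA melanomas of C57BL/6 mice on day 14 and sorted by their binding of the lectin L-Pha. B16-OVA is a mouse melanoma line that expresses ovalbumin, and L-Pha (Phaseolus leucoagglutinin) binds branched N-glycans that carry the branch added by the enzyme Mgat5. The design describes the cells as CD8+ and T cell receptor positive. The comparison asked how the transcriptome of cells with high L-Pha binding differed from that of cells with low binding, with 3 libraries in each group. Total counts were 3143629, 3315980 and 2610729 in L-Pha low 1, 2 and 3, and 3521117, 3439218 and 2819262 in L-Pha high 1, 2 and 3.

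The 6 libraries carried T cell transcripts together with RNA of other tumour cells. Cd8a reached 124 ± 35.2 CPM in L-Pha high and 136 ± 80.1 CPM in L-Pha low (SD, n = 3 each), and Cd4 had 0 to 4 counts per library, where the count of 0 in L-Pha low 1 allows up to 3 counts. The list of T cell identity genes held 0.0472% to 0.109% of all counts and differed 2.66-fold in CPM between the highest and the lowest library. The list of melanoma markers held 1.03% to 1.98%. Most of that came from Dct, an enzyme of melanin synthesis named after its values were seen, at 11740 ± 2576 CPM in L-Pha high and 9900 ± 3110 CPM in L-Pha low (log2 fold change 0.25, SE 0.247). Both libraries numbered 3 had the lowest T cell shares, 0.0472% in L-Pha low 3 (95% interval 0.0446% to 0.0499%) and 0.0632% in L-Pha high 3 (0.0603% to 0.0662%), and the highest melanoma shares, 1.82% and 1.98%. A non-coding gene that overlaps a ribosomal RNA repeat, Gm42418, took 9.59% to 24.96% of the counts, with the highest share in L-Pha low 2. Neither the melanoma share nor the T cell share differed between groups beyond the spread (exact permutation p = 0.5 and 1, two-sided, where the smallest possible is 0.1). Genes with a count numbered 15791, 16105 and 16816 in L-Pha low and 17593, 17452 and 16931 in L-Pha high, so the groups were separated (exact permutation p = 0.1, two-sided).

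**Figure D1:**
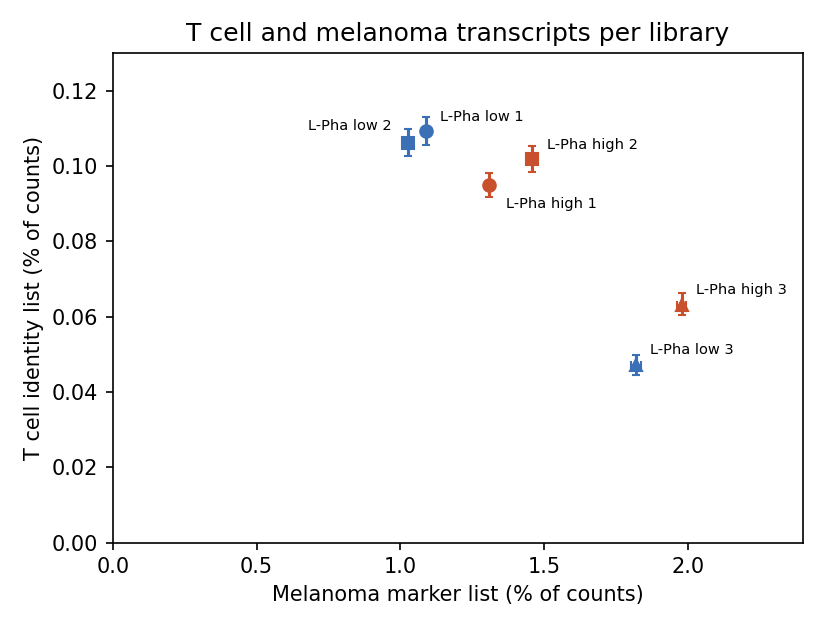
Share of counts of the T cell identity list (y axis, %) against that of the melanoma marker list (x axis, %) in each of the 6 libraries, with exact 95% binomial intervals for counting error. Both libraries numbered 3 lie apart, at 0.0472% and 0.0632% T cell transcripts against 0.0949% to 0.109% in the other 4.

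Transcripts of naive, memory and stem-like T cells were lower in L-Pha high cells. Of the 20 tested members of this list, 19 had lower point values, with a median log2 fold change of -1.27, and 13 were lower in every L-Pha high library than in any L-Pha low library. Adjusted over all genes 1 member fell and 0 rose, and adjusted over the list alone 11 fell and 0 rose (edgeR). DESeq2 called 6 members and limma-voom 0. The member that fell over all genes was Tcf7, which encodes TCF-1, a transcription factor of naive and memory T cells. It had 3.44 ± 0.675 CPM in L-Pha high and 25.3 ± 9.24 CPM in L-Pha low (SD, n = 3 each; log2 fold change -2.86, SE 0.383, edgeR adjusted p = 0.0347; ENSMUSG00000000782, GRCm38 chromosome 11, 52252371 to 52283014). Other members with small p included Nsg2 and S1pr1, which by edgeR fell with adjustment over the list alone and not over all genes. Both were called over all genes by DESeq2 and by edgeR with no count filter, and Nsg2 also without L-Pha low 3. Nsg2 (chromosome 11, 32000463 to 32059202) had 5 counts in the L-Pha high libraries and 73 in the L-Pha low libraries, a ratio of 17.0 with a counting interval of 6.96 to 53.9 (edgeR adjusted p = 0.0982 over all genes). S1pr1, a receptor for egress from tissue, had 2.38 ± 1.54 against 13.6 ± 0.982 CPM (log2 fold change -2.50, SE 0.493).

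The naive, memory and stem-like list was called by camera (adjusted p = 2.1e-22) and also with an estimated correlation (adjusted p = 0.0380), within a range of 3.0e-25 to 0.0380 over its 13 alternatives. For Tcf7 the adjusted p passed in 11 of 18 alternatives and ranged from 5.9e-08 to 0.345. It did not pass with library totals alone (0.0612), with limma-voom (0.257), or without L-Pha low 1 (0.115), L-Pha low 2 (0.217), L-Pha high 1 (0.168), L-Pha high 2 (0.345) or L-Pha high 3 (0.224), and its log2 fold change stayed between -3.01 and -2.51.

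Over all 11183 genes, edgeR called 0 genes higher and 1 gene lower in L-Pha high. At an unadjusted p under 0.05 there were 203 higher and 220 lower genes. DESeq2 called 8 higher and 22 lower genes, of which 10 lower were small nuclear RNA genes that share reads, and limma-voom called 0 in either direction, with 363 and 420 genes at an unadjusted p under 0.05. Without L-Pha low 3, the library with the lowest T cell share, edgeR called 1 higher and 7 lower genes, and without any other single library it called 0. With a block on the libraries' numbers, which the labels do not state to be pairs, it called 20 higher and 23 lower genes. Of those lower genes 10 were small nuclear RNA genes. In 8.41% of genes the groups did not overlap, where chance gives 10%.

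The genes with the smallest p in the upward direction did not pass the threshold over all genes by edgeR with its count filter and group as the only term. Serpine2, a serine protease inhibitor (chromosome 1, 79794197 to 79861180), stood at 159 ± 40.9 CPM in L-Pha high and 43.3 ± 18.8 CPM in L-Pha low (log2 fold change 1.87, SE 0.332, edgeR adjusted p = 0.0982). Gipc2 (chromosome 3, 152093533 to 152166230) had 95 counts against 9, a ratio of 9.06 with a counting interval of 4.58 to 20.4 (edgeR adjusted p = 0.0982). Il1r2, a decoy receptor for interleukin-1, had a log2 fold change of 1.87 (SE 0.359), Galnt18, of the family of O-glycan initiating transferases, one of 2.27 (SE 0.501), and Nr4a2 one of 1.20 (SE 0.272), with edgeR adjusted p-values of 0.165, 0.257 and 0.258. Il1r2 was also a member of the neutrophil marker list, and which cells its RNA came from was not determined. In the downward direction Cxcr3, a chemokine receptor of effector T cells, stood at 2.59 ± 1.24 against 16.1 ± 5.91 CPM (log2 fold change -2.59, SE 0.454). Gzma, which encodes granzyme A, stood at 5.27 ± 1.39 against 26.9 ± 13.6 CPM (log2 fold change -2.34, SE 0.413). Both had an edgeR adjusted p of 0.0982. All of these genes, chosen by small p, were separated between groups in the 6 libraries, which that choice makes likely. DESeq2 called all of them over all genes except Galnt18, edgeR called all of them with no count filter or with a covariate for T cell identity added after seeing the data, and Serpine2, Cxcr3 and Gzma also passed without L-Pha low 3.

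**Figure D2:**
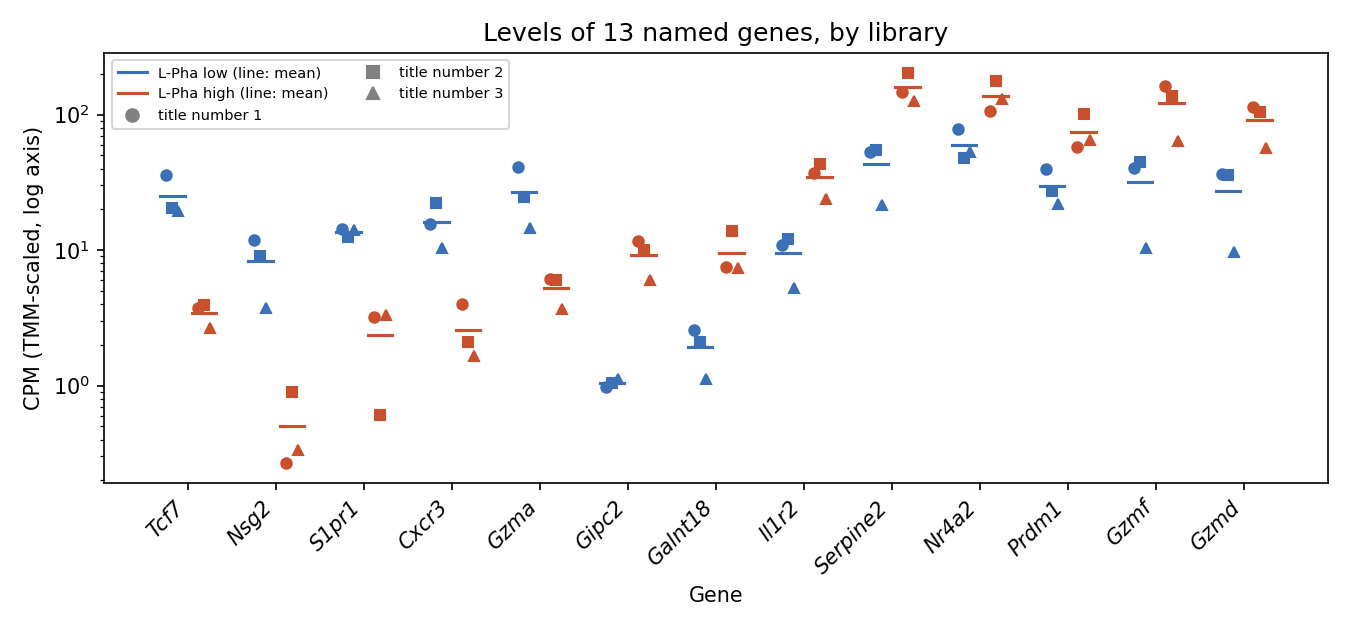
CPM (log axis) of 13 genes in each library, L-Pha low in blue and L-Pha high in red, with symbols for the library number and a line at the group mean. Tcf7 lay at 3.44 CPM on average in L-Pha high and 25.3 CPM in L-Pha low, and Serpine2 at 159 and 43.3 CPM.

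Cytotoxic effector transcripts were higher in L-Pha high as a list by camera at the preset correlation, with granzyme A as an exception. The list was not called with an estimated correlation (adjusted p = 0.798 with an estimated correlation, range over 13 alternatives 1.3e-10 to 0.909). Of 23 tested members 19 had higher point values, with a median log2 fold change of 0.41. None passed over all genes by edgeR, with 8 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom, and adjusted over the list alone 6 rose (Gzmc, Gzmd, Gzme, Gzmf, Gzmg and Klrc1) and 1 fell (Gzma) by edgeR. With no count filter edgeR called these 7 over all genes, and with the T cell identity covariate it called members that included Gzma and Gzmc to Gzmg. Gzmf had 122 ± 51.6 CPM in L-Pha high and 31.9 ± 18.7 CPM in L-Pha low (log2 fold change 1.93, SE 0.445), and Gzmd 91.8 ± 31.1 and 27.4 ± 15.3 CPM. The counts of these granzymes share reads. Summed into 1 row, Gzmc to Gzmg had 443 ± 169 and 129 ± 77.1 CPM, with a log2 fold change of 1.78 (SE 0.456, edgeR adjusted p = 0.483). Klrc1, which encodes the inhibitory receptor subunit NKG2A and shares reads with Klrc2, had 510 ± 259 and 217 ± 14.4 CPM (log2 fold change 1.23, SE 0.315, and 0.77 without L-Pha high 2). Gzmb, the granzyme B gene, did not differ beyond the spread at 195 ± 91.8 and 171 ± 124 CPM (log2 fold change 0.19, SE 0.539), and its log2 fold change was -0.28 without L-Pha low 3 and -0.27 without L-Pha high 1.

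Inhibitory receptors and exhaustion factors were likewise higher as a list by camera at the preset correlation. This list was not called with an estimated correlation either (adjusted p = 0.798 with an estimated correlation, range over 13 alternatives 2.6e-09 to 0.909). Point values were higher for 13 of 15 tested members, with a median log2 fold change of 0.56 (1.48-fold). Adjusted over all genes 0 members rose by edgeR, with 5 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. Adjusted over the list alone 2 rose, Nr4a2, an orphan nuclear receptor induced by receptor signalling, and Prdm1, which encodes the effector regulator Blimp-1 (edgeR). Both passed over all genes by DESeq2 and by edgeR with no count filter or with the covariate. Nr4a2 stood at 138 ± 35.5 and 59.7 ± 16.3 CPM and Prdm1 at 74.6 ± 23.9 and 29.7 ± 9.13 CPM (log2 fold change 1.32, SE 0.301). Of the receptors, Havcr2 (TIM-3) had a log2 fold change of 0.80 (SE 0.361), Cd244a one of 1.32 (SE 0.445), Entpd1 (CD39) one of 1.11 (SE 0.450) and Pdcd1 (PD-1) one of 0.27 (SE 0.401), and none of these passed. The log2 fold change of Havcr2 was 0.47 without L-Pha low 3 and 1.31 without L-Pha low 1.

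At the preset correlation camera gave an adjusted p of 2.5e-05 for the cytotoxic list and 2.9e-05 for the inhibitory list, and fry called neither (0.909 for each). Without L-Pha low 3, the library with the lowest share of T cell transcripts, both calls ended (adjusted p = 0.358 and 0.0814), with medians of 0.24 and 0.38, while the median of the T cell identity list was -0.61. The cytotoxic median was 0.88 without L-Pha low 1, and the inhibitory median was 0.34 without L-Pha high 2.

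Among the other T cell lists, activation and costimulation had a median log2 fold change of 0.37 and was not called (camera adjusted p = 0.408, range over alternatives 0.0162 to 0.985). It was called higher without L-Pha low 1 (adjusted p = 0.0216), without L-Pha high 3 (0.0190) and with the T cell identity covariate (0.0162). Its median was 0.00 without L-Pha low 3, 0.09 without L-Pha high 2 and 0.04 with no count filter. Members with small p included Egr1 (log2 fold change 0.57, SE 0.240) and Tnfrsf9, which encodes the costimulatory receptor 4-1BB (1.05, SE 0.478). Tnfrsf9 passed over all genes with the covariate, at 1.40, and its log2 fold change was 0.61 without L-Pha low 3. Tissue residency and migration was not called (camera adjusted p = 0.908). Adjusted over the list alone 2 of its 17 members fell, Cxcr3 and the integrin gene Itgb7 (edgeR), and Itgb7 stood at 6.15 ± 2.73 against 22.8 ± 3.38 CPM. Both passed over all genes by DESeq2 and by edgeR with no count filter or with the covariate. The median of this list was 0.08, while its mean was -0.17 and the test pointed down. That median was -0.16 without L-Pha low 3, -0.01 without L-Pha high 1, -0.02 without L-Pha high 2 and 0.33 without L-Pha low 1. Of 13 chemokine and cytokine genes 1 rose adjusted over the list alone (edgeR), the growth factor gene Areg, with 74 counts against 12. Of the 74 counts 50 came from L-Pha high 1, and without that library the log2 fold change of Areg was 1.44 against 2.33 with it. The list was not called (camera adjusted p = 0.967, range 0.0312 to 1), but was called lower without L-Pha low 3 (0.0312). Its median was -0.03, while its mean was 0.00 and the test pointed up.

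None of the enzymes that make the sugars bound by L-Pha passed the test by edgeR. Mgat5, the enzyme that adds the branch (ENSMUSG00000036155, chromosome 1, 127205015 to 127488336), stood at 25.4 ± 4.57 CPM in L-Pha high and 22.9 ± 9.22 CPM in L-Pha low (log2 fold change 0.16, SE 0.318). The enzymes before it in the pathway had log2 fold changes of -0.18 for Mgat1 (SE 0.254), -0.36 for Mgat2 (SE 0.264) and 0.20 for Man2a1 (SE 0.386). Mgat2 was lower in every L-Pha high library than in any L-Pha low library, at 21.1 ± 2.51 against 27.0 ± 1.81 CPM. Mgat4a, which adds another branch, had 0.11 (SE 0.322) and Mgat3, which adds the bisecting residue, 0.80 (SE 0.547), from 0.29 without L-Pha high 1 to 1.52 without L-Pha low 1. Of the 19 tested members of the N-glycan branching and galactose extension list 8 were higher and 11 lower in point value, with a median of -0.04, or 0.08 with library totals alone, where the median of all genes was 0.10. None passed over all genes, over the list alone or at an unadjusted p under 0.05 by edgeR, nor by DESeq2 or limma-voom (camera adjusted p = 0.882). Without L-Pha low 1 the log2 fold change of Mgat5 was -0.02, and without L-Pha low 3 it was 0.53. In the libraries numbered 3, T cell identity genes differed by -1.08 in mean log2 CPM from the other libraries. There the N-glycan branching list differed by 0.11, and the other glycan lists by -0.24 to 0.25. These lists thus did not follow the T cell share, and how much of their RNA came from T cells was not determined.

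The other 5 glycan lists were not called by camera, with adjusted p-values of 0.967 for oligosaccharyltransferase and lipid-linked oligosaccharide genes, 0.967 for UDP-GlcNAc synthesis and Golgi sugar transport, 0.440 for sialylation, 0.738 for mucin-type O-glycan initiation and cores, and 0.447 for galectins. None of the 90 tested members of the 6 glycan lists passed over all genes or over its list alone by edgeR, with 6 at an unadjusted p under 0.05, or by DESeq2 or limma-voom. The medians of the oligosaccharyltransferase and O-glycan lists were -0.03 and -0.09, while their means were 0.02 and 0.04 and the tests pointed up, and with library totals alone the medians were 0.08 and 0.02, below that of all genes. fry's test for change in either direction called the O-glycan list (adjusted p = 0.0179), the tissue residency list (0.0180) and the naive list (0.00651). Single genes with small p-values went both ways. The sialyltransferases St3gal1 and St6gal1 had log2 fold changes of -0.97 (SE 0.426) and -0.65 (SE 0.296). Among O-glycan genes Galnt10 had -1.46 (SE 0.453), Gcnt1, which makes the core structure extended on activated T cells, 0.82 (SE 0.306), Fut7, a fucosyltransferase, 1.06 (SE 0.454) and Galnt1 0.58 (SE 0.251). In counts simulated for this comparison with 200 genes changed, edgeR recovered 21% of genes changed 2-fold. Smaller differences in these enzymes were thus mostly not detectable at this depth and spread. With 1 gene called in the real counts, the adjustment was stricter than in the simulation. Serpine2, at 3.67-fold, did not pass (edgeR adjusted p = 0.0982), so larger differences could be missed too. The simulation changed each gene's level in the whole library. How much of these enzymes' RNA came from T cells was not determined, so a difference within T cells could appear smaller in these mixed libraries.

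Interferon response, ribosomal and mitochondrial transcripts were lower in L-Pha high as lists by camera at the preset correlation, by small amounts. None was called with an estimated correlation (adjusted p = 0.337, 0.798 and 0.798 with an estimated correlation) or by fry (0.554, 0.909 and 0.909). The type I interferon list had a median log2 fold change of -0.28, with 19 of 28 members lower; adjusted over all genes 0 fell, with 5 at an unadjusted p under 0.05, and adjusted over the list alone 2 fell, Ifi206 and Ifi208, of the neighbouring interferon-inducible p200 family (edgeR). Ifi206 stood at 2.51 ± 0.768 against 9.54 ± 4.37 CPM, and Ifi213 of the same family, which did not pass, had a log2 fold change of -1.70 (SE 0.553). Cytosolic ribosomal protein genes had a median of -0.24, with 52 of 58 lower, 4 at an unadjusted p under 0.05 and 0 passing over all genes or the list alone (edgeR). This median was -0.15 without L-Pha low 2 and -0.32 without L-Pha low 3. The list took 8.35 ± 0.174% of counts in L-Pha high and 9.03 ± 0.477% in L-Pha low (exact permutation p = 0.1, two-sided, the smallest possible). Rps19 had a log2 fold change of -0.44 (SE 0.198), and Rps27, which shares reads with a copy, one of -0.81 (SE 0.255). Mitochondrially encoded transcripts had a median of -0.21, which was -0.10 without L-Pha high 2, -0.38 without L-Pha low 2 and -0.40 without L-Pha high 3, with 14 of 15 lower, 1 at an unadjusted p under 0.05 and 0 passing over all genes or the list alone (edgeR), and mt-Co3 had a log2 fold change of -0.61 (SE 0.201). Cell cycle genes had a median of 0.16, with 29 of 45 higher, 2 at an unadjusted p under 0.05 and 0 passing either way (edgeR). When a library was left out, this median ran from 0.06 without L-Pha low 3 to 0.19 without L-Pha low 2. Mki67, Gins2 and Plk1 had log2 fold changes of 0.25 (SE 0.258), 0.76 (SE 0.244) and 0.57 (SE 0.245). DESeq2 and limma-voom called 0 members of these 4 lists.

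camera called these 4 lists with adjusted p-values of 3.4e-04 for interferon, 1.6e-05 for ribosomal, 0.00352 for mitochondrial and 0.0321 for cell cycle genes. The cell cycle list was not called with an estimated correlation either (adjusted p = 0.798 with an estimated correlation). The highest adjusted p over their 13 alternatives were 0.554 for interferon and 0.909 for the others, the lowest being 1.1e-04, 2.4e-07, 5.2e-05 and 0.00392 in the same order. The mitochondrial call ended without L-Pha low 3 (adjusted p = 0.205, median -0.25) and without L-Pha high 2 (0.203, median -0.10). The cell cycle call ended without L-Pha low 1 (adjusted p = 0.0889), L-Pha low 3 (0.348), L-Pha high 2 (0.203) or L-Pha high 3 (0.115), and with protein-coding genes only (0.0501), an alternative added after seeing the data. In the libraries numbered 3, T cell identity genes differed by -1.08 in mean log2 CPM from the other libraries. There the interferon, ribosomal, mitochondrial and cell cycle lists differed by 0.01, -0.23, 0.35 and -0.03. Which cells the RNA of these lists came from was not determined.

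**Figure D3:**
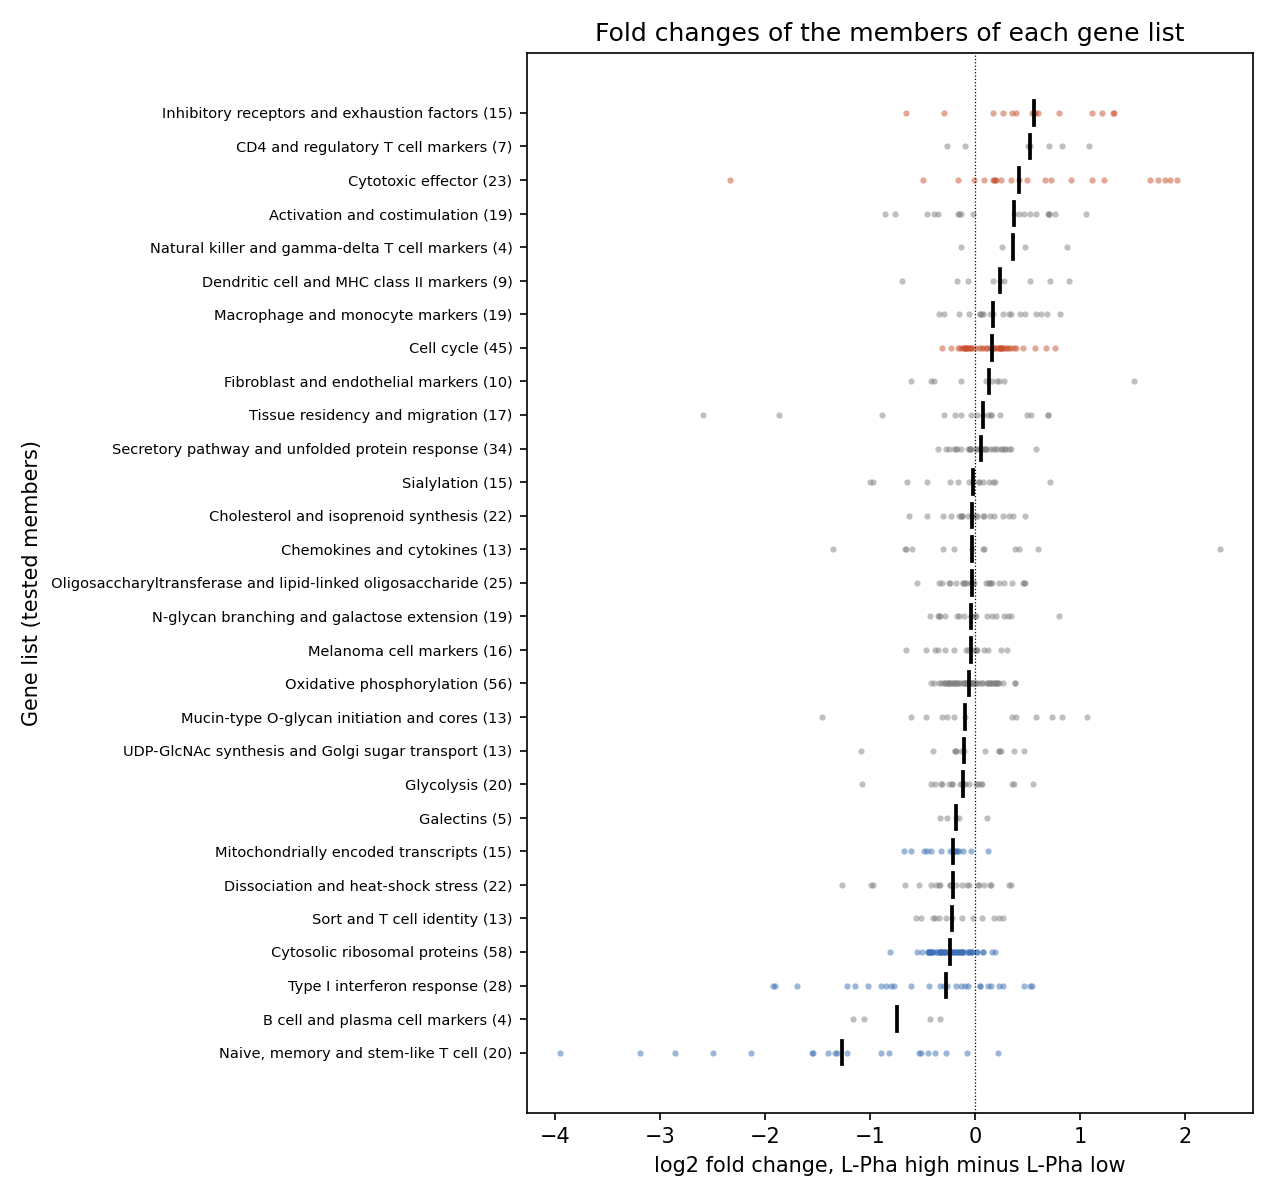
Log2 fold changes (x axis, L-Pha high minus L-Pha low) of the tested members of 29 gene lists (y axis, number of members in parentheses), with a black line at each median. Lists called by camera at the preset correlation are red where higher and blue where lower, and the other lists are grey. The naive, memory and stem-like list has the lowest median, -1.27, and the inhibitory list the highest, 0.56.

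Lists of markers of the sort and of other cells were not called by camera at the preset correlation with all 6 libraries and all tested genes. T cell identity genes had a median log2 fold change of -0.22 with 9 of 13 lower and 0 passing by edgeR, at an unadjusted p under 0.05, by DESeq2 or by limma-voom (camera adjusted p = 0.868, range over alternatives 0.00177 to 0.989). Without L-Pha low 3 this list was called lower in L-Pha high (adjusted p = 0.00177), with a median of -0.61. The median was 0.13 without L-Pha low 2, 0.01 with limma-voom, 0.06 with the deposited log2 table and 0.05 with the covariate. Cd8a, Cd8b1, Cd3e and Trbc2, coding for parts of the CD8 and T cell receptor complexes, had log2 fold changes of -0.13 (SE 0.376), -0.40 (SE 0.393), -0.34 (SE 0.428) and -0.57 (SE 0.323), and Cd8a was 0.01 with library totals alone. Over the alternatives Cd8b1 ran from -0.76 to -0.09 and Trbc2 from -0.90 to -0.34. camera gave adjusted p-values of 0.408 for melanoma markers, 0.0661 for macrophage and monocyte markers, 0.383 for dendritic cell and MHC class II markers, 0.408 for B cell and plasma cell markers, 0.967 for fibroblast and endothelial markers, 0.0664 for CD4 and regulatory T cell markers, and 0.175 for natural killer and gamma-delta T cell markers. Macrophage markers had a median of 0.17, from -0.05 without L-Pha low 2 to 0.38 without L-Pha high 2, led by C1qa (log2 fold change 0.63, SE 0.296, and 0.34 without L-Pha low 1), and B cell markers a median of -0.75, led by Ighm (log2 fold change -1.06, SE 0.469). The mean log2 CPM of the B cell list was 5.14 in L-Pha low 3 and 2.57 to 3.96 in the other 5 libraries. Neutrophil markers were not tested as a list, since 2 of the 14 genes passed the filter. These included Il1r2, which was higher in L-Pha high (log2 fold change 1.87, SE 0.359). Whether neutrophil RNA differed between the groups was therefore not determined.

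Other settings gave calls for several of these lists. With all 6 libraries, macrophage markers were called higher with the stricter filter (camera adjusted p = 0.0472) and with the T cell identity covariate (0.0430), and CD4 and regulatory T cell markers with the covariate (9.8e-04), which was added after seeing the data. Macrophage markers were also called higher without L-Pha low 3 (camera adjusted p = 0.0154) and without L-Pha high 2 (0.00370), within a range of 0.00370 to 0.909 over their alternatives. B cell markers were called lower without L-Pha low 1 (4.1e-04, range 4.1e-04 to 0.985), and melanoma markers without L-Pha high 3 (0.0363, range 0.0363 to 0.985). Fibroblast and endothelial markers were called higher without L-Pha high 2 (0.0309, range 0.0309 to 0.989). CD4 and regulatory T cell markers were called higher without L-Pha low 1 (0.0216), L-Pha low 2 (0.00377) or L-Pha high 3 (0.00746), within a range of 9.8e-04 to 0.909. Natural killer and gamma-delta T cell markers were called higher without L-Pha low 2 (0.00638) or L-Pha high 3 (0.0379), within a range of 0.00638 to 0.909. With all 6 libraries, the CD4 and regulatory T cell list was tested on 7 of its 11 genes, without Cd4 and Foxp3. The natural killer list was tested on 4 of its 18 genes, without Ncr1. Calls of these lists therefore do not decide whether such cells differed between the groups.

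The remaining lists were not called by camera, with adjusted p-values of 0.408 for glycolysis, 0.611 for oxidative phosphorylation, 0.967 for cholesterol and isoprenoid synthesis, 0.491 for the secretory pathway and unfolded protein response, and 0.223 for dissociation and heat-shock stress. Their medians lay between -0.21 for heat-shock stress and 0.06 for the secretory pathway, and those of glycolysis, oxidative phosphorylation and cholesterol synthesis were 0.01, 0.06 and 0.09 with library totals alone, below that of all genes. Heat-shock stress genes were called lower without L-Pha low 3 (camera adjusted p = 0.0154, range over alternatives 0.0154 to 0.985).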

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

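The covariate for T cell identity and the restriction to protein-coding genes were chosen after seeing the data. Against 0 higher genes by edgeR, there were 20 with no count filter, 8 with DESeq2, 20 with the identity covariate, and from 0 to 1 when a library was left out. Against 1 lower gene, there were 27 with no count filter, 22 with DESeq2, 21 with the covariate (10 of each being small nuclear RNA genes that share reads), 0 with limma-voom, 0 with library totals only, and from 0 to 7 when a library was left out, with 7 without L-Pha low 3. Against 7 lists called, camera with an estimated correlation and fry each called 1, the naive list, and the other alternatives called 6 to 10. The cause of these shifts was not tested. Scaling by library totals moved the median log2 fold change of all genes from -0.01 to 0.10. The 7 called lists kept their direction, and the medians of N-glycan branching (0.08), oligosaccharyltransferase (0.08), UDP-GlcNAc (0.02), sialylation (0.08), O-glycan (0.02), chemokine (0.08), cholesterol (0.09), glycolysis (0.01), oxidative phosphorylation (0.06) and melanoma genes (0.07) turned positive but lay below that of all genes, so relative to the shift they stayed negative.

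The numbers 1, 2 and 3 were also fitted as a replicate block, which gave 20 higher and 23 lower genes, 10 of them small nuclear RNA genes, and 8 lists, adding CD4 and regulatory T cell markers (adjusted p = 0.0109, range 9.8e-04 to 0.909). Genes that passed with the block included Serpine2, Gipc2, Il1r2, Nr4a2, Prdm1, Gzmd, Gzmf, Klrc1, Tnfrsf9, Penk, Serpinb9b and Rbpj upward and Tcf7, Nsg2, S1pr1, Cxcr3, Gzma, Itgb7 and Cd7 downward. The deviations from the group means correlated at 0.37, 0.08 and 0.47 between libraries with the same number. Every L-Pha high library correlated best with the L-Pha low library of its own number. L-Pha low 1 and L-Pha low 3 likewise correlated best with their own number, and L-Pha low 2 did not. The libraries numbered 1 and those numbered 3 thus deviated together. The labels state no pairing, so the main fit has no block, and whether the libraries are paired is left open.

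Among named genes that did not pass, some log2 fold changes changed sign. Cd8a turned to 0.0111 with library totals only, 0.0317 with limma-voom, 0.0657 with the deposited log2 table, 0.0112 with the block and 0.0840 with the covariate, and Ms4a1 to 0.0824 with limma-voom, 0.0511 with the deposited table, 0.0217 with the block and 0.113 with the covariate. When a library was left out, Cd8a ran from -0.490 to 0.384, Cd3e from -0.721 to 0.121, Pdcd1 from -0.0935 to 0.567, Gzmb from -0.279 to 0.770, Mgat5 from -0.0154 to 0.534, Mgat4a from -0.179 to 0.268, Man2a1 from -0.0647 to 0.567, Ms4a1 from -0.814 to 1.035 and Cd74 from -0.448 to 5.8e-04, and the chemokine list's adjusted p from 0.0312 to 0.897. Depth limits genes with few counts most, such as Nsg2 with 5 counts in L-Pha high and Areg with 12 in L-Pha low.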

Other observations

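Further genes outside the rule, chosen after their values were seen, were separated between the groups. They did not pass over all genes by edgeR with its count filter and group as the only term. With no count filter, with the block or with the T cell identity covariate Cd7, Penk and Serpinb9b passed. Cd7 also passed by DESeq2, and Rbpj passed with the block. Cd7, a surface receptor of T cells, stood at 4.40 ± 3.24 CPM in L-Pha high and 17.7 ± 6.67 CPM in L-Pha low (edgeR adjusted p = 0.345), with 44 against 153 counts. Penk, the preproenkephalin gene, stood at 57.3 ± 21.7 and 21.4 ± 13.1 CPM (log2 fold change 1.41, SE 0.444, edgeR adjusted p = 0.803), and Serpinb9b, of a family of granzyme inhibitors, at 55.7 ± 5.94 and 22.1 ± 9.81 CPM (log2 fold change 1.32, SE 0.326). Rbpj, the DNA-binding partner of Notch, stood at 87.9 ± 11.5 and 46.1 ± 1.62 CPM (log2 fold change 0.93, SE 0.229), and shares reads with its pseudogene Rbpj-ps3 (1.15, SE 0.277). Of 39 small nuclear RNA genes tested, 30 were lower in every L-Pha high library than in any L-Pha low library, 27 had an unadjusted p under 0.05 and 0 passed with adjustment (edgeR), while 10 were called lower with no count filter, 10 with the covariate and 10 by DESeq2, the same reads being counted at several copies.

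The tests below were chosen after the result was seen, except the splits of the libraries, the summed granzymes and the totals without Gm42418. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 1 gene, and the highest other split called 415, with 2 of the 10 calling at least 1. For lists the real split called 7 and the highest other 14, with 7 of the 10 calling at least 7. The number of lists called at the preset correlation was thus no larger than most other splits gave. The split with 415 genes set L-Pha low 1, high 1 and low 2 against L-Pha high 2, low 3 and high 3, which points to a structure of the libraries other than the groups.

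Naive, memory and stem-like transcripts were lower in L-Pha high. In the libraries numbered 3, where T cell identity genes differed by -1.08 from the other 4, the naive list differed by -0.21, so a lower share of T cell RNA would lower this list by no more than the identity list. Relative to identity the naive list differed between the groups by -1.14, with the groups separated, and by -0.76 without L-Pha low 3. These values argue against that share as the whole cause. Without L-Pha low 3, where B cell markers were highest, the B cell list had a median of 0.42 and the naive list one of -1.33. Log2 fold changes were then 1.03 for Ms4a1, -0.32 for Ighm and 0.00 for Cd74. These values argue against B cells as the source of the lower naive list, although B cell transcripts were present in the sorted libraries. With all libraries Ms4a1, Ighm and Cd74 stood at 13.1, 16.1 and 13.1 CPM in L-Pha high and 16.7, 33.9 and 14.9 CPM in L-Pha low. More T cells of a naive or memory state in the L-Pha low gate remains a hypothesis, which no test here decides.

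Inhibitory receptor and cytotoxic transcripts were higher in L-Pha high by camera at the preset correlation, but neither list was called with an estimated correlation (adjusted p = 0.798 for each) or without L-Pha low 3 (0.0814 and 0.358). Relative to T cell identity genes the inhibitory list differed by 0.62 and the cytotoxic list by 0.74, with the groups separated. Without L-Pha low 3 the lists differed by 0.80 and 0.71. In that setting the median log2 fold changes of the lists themselves were 0.38 and 0.24, and that of the identity list was -0.61. Part of the 0.80 and 0.71 thus came from the lower identity list. These values argue against a higher share of T cell RNA. Counting the same reads at several granzymes does not by itself give the cytotoxic call at the preset correlation, which held with these rows summed. The camera adjusted p was then 0.0118, against 2.5e-05 with the rows apart and a range over the alternatives of 1.3e-10 to 0.909. A difference in T cell state between the gates remains a hypothesis, which no test here decides.

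T cell transcripts were lower in the libraries numbered 3, whose T cell identity list had a mean log2 CPM lower by 1.08 (difference -1.08) than in the other 4. A lower share of T cell RNA is a candidate explanation, since the lists of melanoma, macrophage, MHC class II, B cell and fibroblast markers were all higher there on average, by 0.27 to 0.68. Against this, B cell markers were highest in L-Pha low 3 (5.14) and lowest in L-Pha high 3 (2.57), and macrophage markers (5.02 and 4.99) lay within the range of the other libraries. Gm42418 does not account for it, as the highest share of T cell transcripts remained 2.64 times the lowest with that gene left out of the totals. Whether the number marks a pool, a sort or a day is not given in the sources used here, and no biological explanation was tested.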
